A study of Caenorhabditis elegans with 2 samples.

How the data were processed

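ChIP-seq of tagged NHR-25 was performed in L3 larvae of Caenorhabditis elegans in 2 samples, which the labels number as biological replicates 1 and 2 of a single group; no second condition was analysed here. The immunoprecipitated target is labelled as NHR-25, which the strain carries as a fusion to GFP and FLAG. Per the labels, chromatin was fragmented by sonication. The antibody field names nhr-25 only. The extraction protocol, aligner and peak caller are not given in the sources used here.

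The authors deposited peak lists on the ce10 and ce11 assemblies. Per the deposited index text, each replicate list was derived from the alignment of that replicate and a control alignment, the pooled list from the alignments of both replicates and the control, and the IDR list from the pooled list and both replicate lists. Peaks were therefore called both per sample and on pooled samples. Every replicate or pooled list held 30000 regions, including background regions meant as input for the IDR step, so the length of these lists says nothing about binding. The authors' signal column gives a height per peak whose scale is not given in the sources used here and may rise with depth. The authors' q-value column, on the −log10 scale, was at its maximum of 3.86 for 71.8% of the IDR peaks, so peaks were ranked by signal and not by q-value. Each region also carries a deposited offset to its summit. Control lists, read counts and signal tracks were not used here, so depth per sample is unknown, no enrichment over input was computed and no floor based on reads can be given. Intervals on shares cover counting of peaks or genes only.

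All 5017 IDR peaks on ce11 were found in the pooled list, and they were exactly its 5017 highest-signal regions. They span 5014 distinct intervals, a few of which are listed with more than 1 summit. No region was identical between the replicate lists, so the samples were treated as separate. Peak positions were used on ce11, the same assembly as the reference genome, with genes from Ensembl release 115; ce10 lists were used for counts and for overlaps within ce10 only. Coordinates are 1-based.

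Replicates were compared by the share of the 5017 highest-signal peaks of replicate 1 with a summit within 100 bp of one of the 5017 highest-signal peaks of replicate 2, against 1000 random placements. Signals were compared by Spearman's rho and by Pearson's r of log2 signal, across IDR peaks with a summit within 100 bp in both replicate lists. Summits were assigned in order to a promoter window (2000 bp upstream to 200 bp downstream of a protein-coding gene's 5′ end, as annotated), coding exon, other exon, intron, non-coding gene or intergenic sequence, piRNA genes left out, and set against 1000 random placements on the same chromosome. Peak density on X was tested with a two-sided exact binomial test on assembled length. The element YCAAGGYCR was searched on both strands within 100 bp of each summit and in windows centred 1000 bp to each side, with a two-sided exact sign test of discordant peaks, and the reversed pattern RCYGGAACY served as control. Annotated 5′ ends were used as such, although many transcripts of this species are trans-spliced and the true start can lie upstream.

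Gene lists were tested with Fisher's exact test, two-sided, for the share of members with an IDR summit in the promoter window against all other nuclear protein-coding genes, with Benjamini-Hochberg adjustment over 20 lists and a threshold of 0.05. Lists were molting, named and numbered cuticle collagens, epidermal and seam transcription factors, epidermal junction and fusion genes, hedgehog-related genes, heterochronic, vulval, Wnt and Hox genes, nuclear hormone receptors, lipid genes, markers of intestine, body wall muscle, pharynx, neurons and germline, ribosomal proteins, histones and chemoreceptors. Some genes stand in more than 1 list, and nhr-25 was left out of all. A summit can fall in the windows of several genes, as did 1032 of 2870 promoter summits (36.0%), so genes are not independent and p-values describe this peak list. Peaks within 20 kb of nhr-25 and unc-119 were counted against 1000 random windows, and summits within 200 bp of tRNA genes against 1000 random placements. For single replicates, the 5017 highest-signal peaks of each took the place of the IDR list.

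Named genes were those assigned to the 10 strongest IDR peaks (promoter window, else the nearest gene), up to 4 members of each list with the strongest promoter peak, the first 2 members without one in lists given by name, and nhr-25, nhr-23, unc-119 and acs-3. Lists, tests and this rule were fixed before the data were examined. Alternatives were other match distances and numbers of top peaks, the ce10 lists, the 2508 IDR peaks of highest signal, the pooled list, each replicate left out, promoter windows of 1000 and 500 bp, assignment to the nearest 5′ end, 10000 random lists matched on upstream length, other search windows, flank and core pattern, 10 kb around the loci and 500 bp around tRNA genes.

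The measures were tested on simulated data with 5017 summits. A planted replicate overlap of 70.3% was measured as 70.6%. An element planted at 9.85% of summits was recovered as 10.1% above the flank share. The promoter share was 73.3%, with 73.3% expected. That expected value took its unplanted part from the same measure, so the check covers the planted summits only. Of random lists of 50 genes, 4% passed an unadjusted threshold of 0.05 over 19973 genes. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.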

Results

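Binding of the nuclear hormone receptor NHR-25 was mapped by ChIP-seq in whole Caenorhabditis elegans at the third larval stage (L3). NHR-25 belongs to the SF-1/FTZ-F1 family of receptors and is known for roles in epidermal development and molting. The worms were of both sexes and came from a transgenic strain that stably expressed NHR-25 fused at its C terminus to GFP and FLAG, in an unc-119 mutant background. Chromatin was sheared by sonication. The 2 samples were labelled as separate biological replicates of a single group, so the only comparison among samples was replicate against replicate. All other comparisons set the peaks against random positions or other genes. Each replicate list and the pooled list held 30000 regions, and the list thresholded on the irreproducible discovery rate (IDR) held 5017 peaks on the ce11 assembly. These 5017 peaks were the 5017 regions of highest signal in the pooled list, so a peak's place in the list was set by its pooled height. Read totals were not used here and the depth of each library is therefore unknown. Signal values are the authors' own heights per peak, and were used only to rank and describe peaks.

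Of the 10 strongest peaks, 8 lay in the promoter window of at least 1 protein-coding gene, and the others in introns of nhr-25 and Y111B2A.12. The highest, on chromosome II from 8561302 to 8561571, had its summit in intergenic sequence 75 bp upstream of iff-2, which encodes the translation factor eIF5A. Its signal was 919.6 in the pooled list, 438.7 in replicate 1 and 483.1 in replicate 2, and it ranked highest in all of these lists. The next, on III from 3867429 to 3867713, was intergenic and 280 bp upstream of rpl-3, a ribosomal protein gene, with signals of 805.1 pooled, 395.3 and 418.5. A peak of signal 782.9 on X from 5841021 to 5841463 lay 297 bp upstream of puf-9, a Pumilio-family RNA-binding protein gene, and within the annotated non-coding genes W06B11.7 and W06B11.9. The peak ranked 4 lay inside nhr-25. Others among the 10 strongest lay upstream of tasp-1 (45 bp, signal 708.6), sec-61.G, a subunit of the Sec61 translocon (222 bp, 627.8), rpl-35 (446 bp, 621.3) and cdc-48.1, the p97 AAA ATPase (157 bp, 592.8). A peak on III at summit 4899948, signal 654.8, lay between nhl-2, a TRIM-NHL cofactor of microRNAs, and tag-340, within the non-coding gene F26F4.14. The remaining one, on III from 12612475 to 12612809 with signal 674.9, lay in an intron of Y111B2A.12. Several of these summits also fell in the promoter window of a further gene: F54C9.14 for the iff-2 peak, dct-11 for the puf-9 peak, rnf-113 and K01G5.10 for the tasp-1 peak, F32D8.7 and F32D8.13 for the sec-61.G peak, and C06A1.7 for the cdc-48.1 peak. Each of the 10 ranked 21 or better by signal in either replicate.

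Whether both replicates marked the same sites was asked first. The replicates shared most of their strongest peaks, and the shared part was far above that of random positions. Of the 5017 highest-signal peaks of replicate 1, 3447 (68.7%) had a summit within 100 bp of one of the 5017 highest-signal peaks of replicate 2. Random placement of the replicate 2 summits on their chromosomes gave a mean of 1.03% and at most 1.495% (1000 placements, permutation p = 0.001, the smallest they can give). Of the 1000 IDR peaks of highest pooled signal, 98.6% were among the top peaks of both replicates, against 14.5% of the 1017 weakest. The latter lie near the lower limit of each top list. Pooled signal rises with both replicate signals, so part of this gradient is set by the ranking itself. With peaks ranked per replicate, the overlap was 70.9% when fewer top peaks were taken and 57.3% with 2 times as many. In all, 69.5% of the IDR peaks were among the top peaks of both replicates, and 102 were among those of neither. A summit within 100 bp was found anywhere in the replicate 1 list for 96.0% of IDR peaks, in that of replicate 2 for 97.3%, and in both for 93.4% (4688 peaks). Across these 4688 peaks the 2 signals correlated with Spearman's rho = 0.630 (bootstrap 95% interval 0.610 to 0.648) and Pearson's r = 0.653 on the log2 scale; peaks are not independent replicates. The pooled signal was close to the sum of both replicate signals (median ratio 1.00), so the peaks were selected on that sum, which narrows their range; across all matched regions of the 2 replicate lists rho was 0.766. The log2 ratio of replicate 2 to replicate 1 had a median of 0.11 and an SD of 0.73 across peaks.

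**Figure D1:**
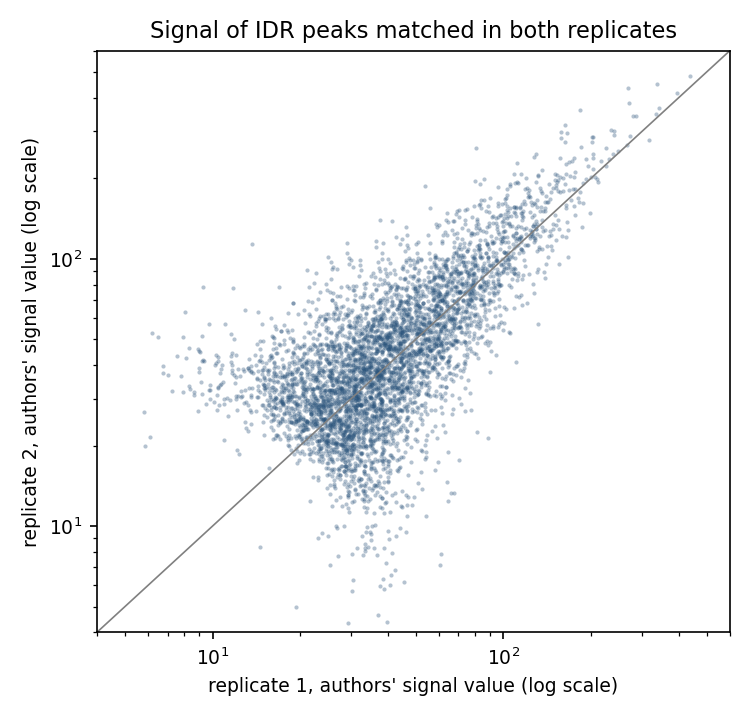
Signal of the 4688 IDR peaks matched in both replicates, replicate 1 on the x axis and replicate 2 on the y axis, both in the authors' signal units on log scales; each point is 1 peak and the line marks equal values. The points spread around the line (Spearman's rho = 0.630), and the strongest peaks are high in both replicates.

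Peaks were more frequent than random positions upstream of protein-coding genes and less frequent in coding sequence. Of the 5017 IDR summits, 2870 (57.2%, exact 95% interval 55.8 to 58.6) lay in a promoter window, from 2000 bp upstream to 200 bp downstream of a protein-coding gene's 5′ end. Random placement gave 35.6% on average and 37.7% at most (1000 placements, permutation p = 0.001, the smallest they can give). The top peaks of each replicate alone gave 56.3% ± 0.21 (SD, n = 2). With a window of 500 bp upstream the share was 36.97%, also above random placement in that smaller window (permutation p = 0.001). The random shares just given are those of the 2000 bp window. Of all summits, coding exons held 2.79% (random positions 16.04%, lowest 14.7%), introns 19.9% (random 27.3%, lowest 25.4%), intergenic sequence 15.9% (random 16.1%), non-coding genes 2.63% (random 2.48%, highest 3.19%) and untranslated or other exons 1.51% (random 2.49%). These shares depend on the promoter share, which was assigned first. Among the 2147 summits outside promoter windows, coding exons held 6.52% (random positions 24.9%, lowest 22.98%), introns 46.5% (random 42.3%, highest 45.0%) and intergenic sequence 37.3% (random 25.05%, highest 27.5%). Non-coding genes held 6.15% (random 3.84%, highest 4.85%) and untranslated or other exons 3.54% (random 3.86%); a share within this part rises where that of coding exons falls. Summits within 500 bp of the nearest 5′ end made up 39.0% of the list, and 84.2% of these were on its upstream side; for random positions the values were 17.9% and 48.4%. Random placement took no account of which sequence reads can be mapped to.

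The X chromosome carried more peaks per length than the autosomes. It held 1085 of the 5017 peaks (21.6%, exact 95% interval 20.5 to 22.8) on 17.7% of the assembled nuclear length. The density was 61.2 peaks per Mb on X and between 37.9 on V and 57.7 on III for the autosomes. The ratio of X to all autosomes was 1.29 for the IDR list, 1.27 for replicate 1 and 1.37 for replicate 2 (exact binomial test, two-sided, p = 8.50e-13 for the IDR list). Peaks are not independent of each other, so this p describes the list only.

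The half-site of the receptor family was enriched at the summits, but few summits carried it. The extended half-site YCAAGGYCR (Y is C or T, R is A or G) lay within 100 bp of 173 of 5017 summits (3.45%, exact 95% interval 2.96 to 3.99). In windows of equal width 1000 bp to either side it was present for 0.638% on the left and 0.638% on the right (exact sign test against the left flank, two-sided, p = 1.33e-24). The top peaks of the single replicates gave 3.28% ± 0.014 (SD, n = 2). The same pattern reversed went the other way, at 0.319% of summits and 0.718% and 1.02% of the flanks. The shorter core CAAGGYC was present at 6.80% of summits against 1.89% and 1.95% of flanks. From the strongest to the weakest peaks, in successive groups of 1004 or 1003, the share with the full element was 3.09%, 4.88%, 3.69%, 2.89% and 2.69%. It was 4.07% in the 2508 strongest peaks and 2.83% in the other 2509 (Fisher's exact p = 1.65e-02, two-sided, a test chosen after these shares had been seen). Within 50 bp of the summit the share was 2.27%. None of the 10 strongest peaks carried it.

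**Figure D2:**
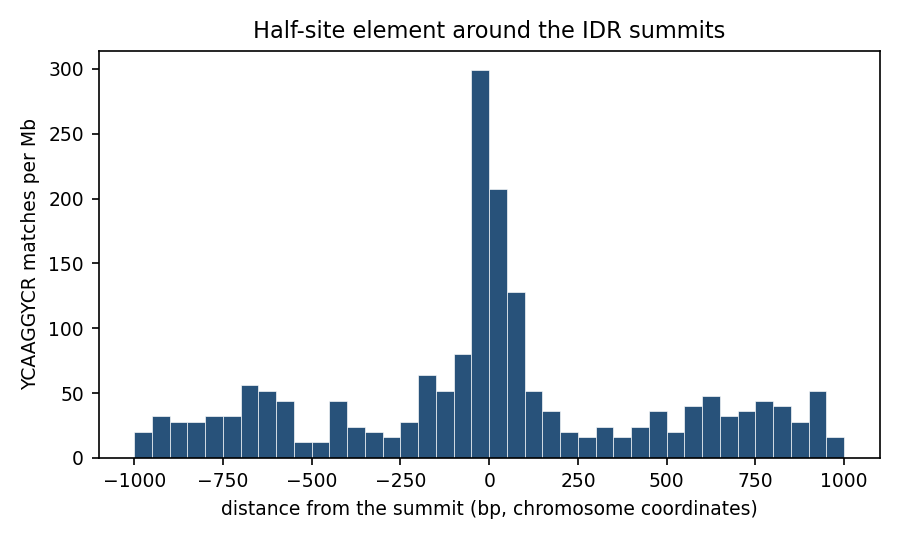
Matches of the half-site element YCAAGGYCR per Mb (y axis) in bins of 50 bp around the 5017 IDR summits (x axis, bp, in chromosome coordinates). The density rises to 299 and 207 per Mb in the bins on either side of the summit.

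Genes of molting, cuticle collagens and epidermal junctions carried promoter peaks more often than other genes. Of 19973 nuclear protein-coding genes, 3673 (18.4%) had an IDR summit in the promoter window. That share takes in families with few promoter peaks, such as chemoreceptors (2.99%). A share above it is not particular to epidermal genes, since 58.7% of 92 ubiquitously expressed genes described further below had such a summit. Of 33 molting genes 15 did (45.5%, exact 95% interval 28.1 to 63.7; 39.4% ± 4.3 in the single replicates, SD, n = 2). Among them were mlt-7, a peroxidase of cuticle assembly (signal 185.9, summit 261 bp upstream), blmp-1, a zinc-finger transcription factor (145.8, 1710 bp upstream), sym-1 (144.1, 43 bp upstream, within an intron of C44H4.4) and myrf-1, a membrane-tethered transcription factor (119.5, 263 bp upstream). mlt-2 and mlt-3 had none. Of the 18 genes of epidermal junctions, attachment and fusion 9 had one (exact 95% interval 26.02 to 73.98%), led by the junction gene let-413 (201.7), the alpha-catenin gene hmp-1 (86.2), vab-19 (72.5) and erm-1 (65.7). dlg-1 and ajm-1 had no promoter peak, though 1 and 5 summits lay within the genes. Of the 20 named cuticle collagens 8 had one (exact 95% interval 19.1 to 63.9%), led by dpy-13 (118.8), dpy-5 (90.5), bli-6 (81.7) and sqt-2 (63.9), while dpy-2 and dpy-3 did not. Of the 156 collagens with col numbers 41 did (26.3%), led by col-94 (236.5), col-38 (218.4), col-145 (205.1) and col-107 (196.2).

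By Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 20 lists, the exact adjusted p was 1.73e-03 for molting (odds ratio 3.71), 7.73e-03 for epidermal junctions (4.45), and 4.45e-02 for both the named collagens (2.96) and the numbered collagens (1.59). The collagen calls rest on thin margins: the named collagens did not pass without replicate 2 (odds ratio 1.95, exact adjusted p = 0.222) nor the numbered ones without replicate 1 (0.205). The numbered ones did pass with windows of 1000 and 500 bp upstream (odds ratios 1.85 and 1.97, exact adjusted p = 9.48e-03 and 6.86e-03). They also passed with nearest-end assignment (2.17, 5.17e-04). The odds ratio of junction genes was 7.27 without replicate 1. Molting and junction genes did not pass with promoter windows of 1000 bp upstream (0.0549 and 0.193) or 500 bp upstream (0.242 and 0.558). Junction genes and both collagen lists also failed in the 2508 strongest IDR peaks (1.00, 0.774 and 0.434), the named collagens with the shorter windows (0.0515 and 0.0774), and both collagen lists against random lists matched on upstream length (permutation, 0.107 and 0.0533). In the shorter windows the odds ratios of the named collagens were 3.31 and 3.39, not below that of the main setting.

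The other epidermal lists were not told apart from all genes. Of the 17 epidermal and seam transcription factors 5 had a promoter peak (29.4%, exact adjusted p = 0.316). Besides blmp-1 these included ceh-16, the engrailed homologue of the seam cells (66.5), nhr-23, a receptor needed for molting (63.6, summit 1128 bp upstream on I), and lin-26 (46.1). elt-1 and elt-3, GATA factors of the epidermis, had none in the window but 2 and 3 summits within the genes. Of the 85 hedgehog-related and patched-related genes 22 had one (25.9%, exact adjusted p = 0.165), led by grl-17 (235.4), ptr-23 (208.7), wrt-1 (150.7) and grl-21 (131.9).

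Genes of developmental timing and of Wnt signalling also carried promoter peaks more often than other genes. Of the 17 heterochronic genes 9 had one (52.9%, exact 95% interval 27.8 to 77.0; exact adjusted p = 5.54e-03, odds ratio 5.002). They were led by nhl-2, ain-1, a GW182-type component of the microRNA complex (294.8, 936 bp upstream), lin-66 (168.2) and lin-41, the TRIM-NHL target of let-7 (141.1, no match in replicate 1). lin-29 and lin-42 had none in the window, although 1 and 7 summits lay within these genes. The heterochronic call was lost only with the window of 500 bp (exact adjusted p = 0.257). Of 31 Wnt pathway genes 11 had one (35.5%, exact adjusted p = 4.45e-02, odds ratio 2.44), led by the Dishevelled genes dsh-2 (288.6, with the half-site at its summit) and mig-5 (218.5), kin-19 (193.7) and apr-1 (161.8). The ligand genes egl-20 and cwn-1 had none. The Wnt call was lost without replicate 2 (exact adjusted p = 0.222), in the 2508 strongest peaks (0.434), with either shorter window (0.153 and 0.534) and against matched random lists (permutation, 0.0600).

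Several lists of known or possible NHR-25 biology showed no difference from all genes that passed the test. Of 32 vulval genes 7 had a promoter peak (21.9%, exact adjusted p = 0.718), among them eor-2 (236.9), let-60, the Ras gene (151.1), lin-7 (131.1) and smo-1, the SUMO gene (100.8), but not lin-3 or let-23. Of 6 Hox genes only ceh-13 did (16.7%, signal 60.4, exact adjusted p = 1.00). lin-39 and mab-5 had none in the window, though 1 summit lay within lin-39. Of 268 other nuclear hormone receptor genes 59 did (22.01%, exact adjusted p = 0.216), led by nhr-14 (373.4), nhr-86 (215.8), nhr-68 (214.4) and nhr-47 (193.3). That list passed only when each summit was given to its nearest 5′ end (exact adjusted p = 1.29e-02). Of 25 genes of fatty acid synthesis and lipid regulation 6 did (24.0%, exact adjusted p = 0.552). The 4 strongest were nhr-49 (159.3), fasn-1 (111.5), fat-2 (90.4) and acs-20 (68.8). fat-1, fat-3 and acs-3, an acyl-CoA synthetase gene, had none in the window, though 1 summit lay within fat-3.

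Ribosomal protein genes had the highest share of all 20 lists, and chemoreceptor genes fell far under the share of all genes. Of 76 ribosomal protein genes 69 had a promoter peak (90.8%, exact 95% interval 81.9 to 96.2; 87.5% ± 0.93 in the single replicates, SD, n = 2), from 67 distinct peaks. The odds ratio was 44.6 and the exact adjusted p 5.89e-42. With each summit given to its nearest 5′ end only, the share fell to 51.3% and the odds ratio to 7.14 (exact adjusted p = 1.05e-14), near the heterochronic (47.1%, 5.96) and molting genes (45.5%, 5.60) under that setting. rps-1 (535.4) and rpl-15 (533.8) followed rpl-3 and rpl-35 in signal. Of 72 histone genes 26 did (36.1%, exact adjusted p = 1.73e-03), from 19 distinct peaks, with his-35 and his-37 sharing a peak of signal 556.1 and his-67 and his-68 one of 301.4. Histone genes are near-identical copies that lie in clusters, so reads may be shared between them, and the call was lost when each summit was given to its nearest 5′ end (exact adjusted p = 9.75e-02) and against matched random lists (permutation, 0.104). Chemoreceptor families are expressed mainly in sensory neurons. Their list was drawn by names starting with sr, which also takes in other genes such as src-2. Of its 1171 genes 35 had a promoter peak (2.99%, exact 95% interval 2.09 to 4.13, exact adjusted p = 1.72e-60, odds ratio 0.128). The strongest of these were srw-67 (191.0), srh-76 (169.3), srt-11 (168.4) and src-2 (136.2). src-2 is a Src-type kinase gene that the list holds only through its name. The ribosomal and chemoreceptor calls passed in all 8 alternative settings, with chemoreceptor odds ratios down to 0.0574 with the window of 500 bp. One of these settings, the strongest pooled regions, holds the same peaks as the IDR list and could not change a call.

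No list of markers of tissues other than the epidermis differed from all genes by the test. None of 15 body wall muscle genes (hlh-1 and myo-3 among them) and none of 12 pharynx genes (pha-4 and myo-1 among them) had one, which allows shares of up to 21.8% and 26.5% (exact 95% upper limits; exact adjusted p = 0.165 and 0.216). With a share of 0 these lists were too short to pass the threshold. The intestine and neuron lists, of 13 and 17 genes, were too short for that as well. Of 13 intestine genes only vha-6 did, with signal 50.4 and its summit 1907 bp upstream (7.69%, exact adjusted p = 0.570); elt-2 and elt-7 had none. Of 17 neuron genes only snb-1 did (129.4; 5.88%, exact adjusted p = 0.456), and rab-3 and unc-13 had none; without replicate 1 the neuron count was 2 and the intestine count 0. Of 28 germline genes 4 did (14.3%, exact adjusted p = 0.849): cgh-1 (134.0), rad-51 (99.4), spo-11 (66.5) and car-1 (43.4), but not glh-1 or glh-2.

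**Figure D3:**
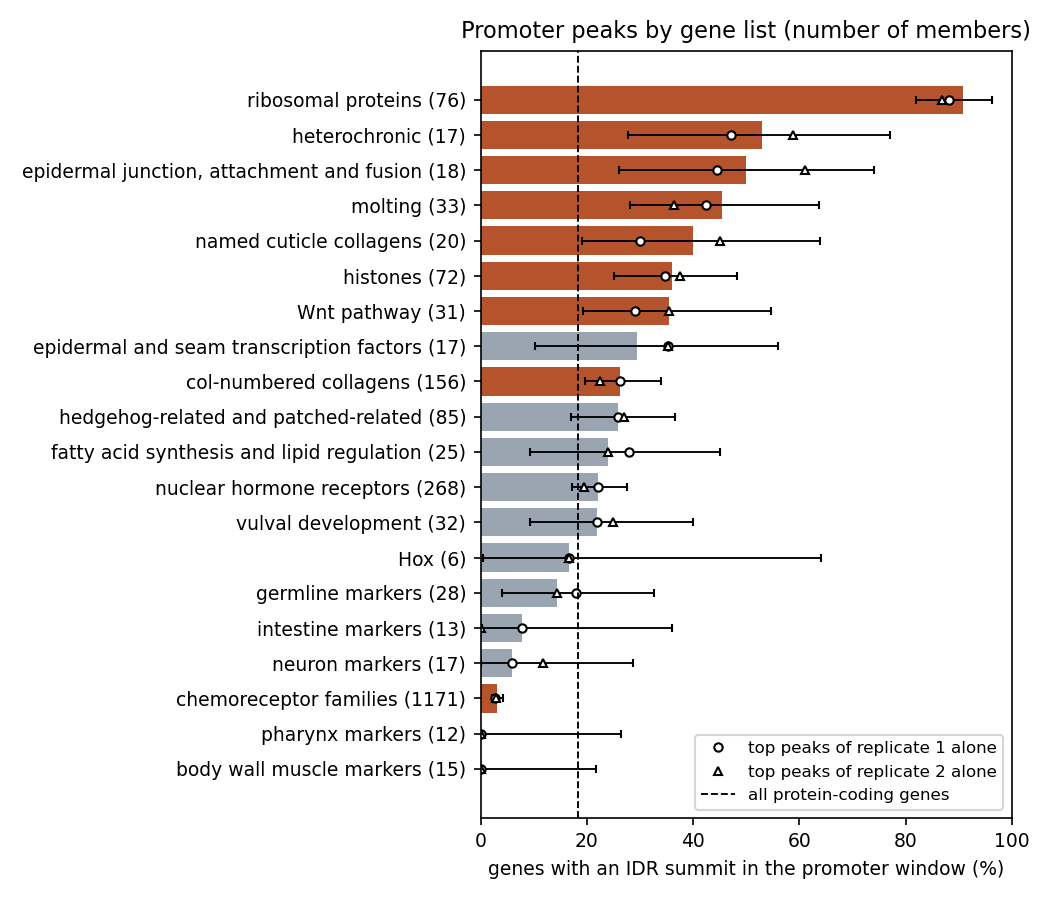
Share of genes with an IDR summit in the promoter window (x axis, %) for the 20 gene lists (y axis, number of members in brackets). Bars give the IDR list with exact 95% intervals, circles and triangles the top peaks of replicates 1 and 2 alone, and the dashed line all protein-coding genes (18.4%); darker orange bars passed the test. Ribosomal protein genes reach 90.8% and chemoreceptor genes 2.99%.

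The nhr-25 locus itself carried a dense run of peaks, whereas unc-119, the marker gene of the strain, carried none. Within 20 kb of nhr-25 (WBGene00003623; X, 13008493 to 13013964, plus strand) lay 15 IDR peaks, against a mean of 2.36 and a highest count of 19 in 1000 random windows of equal width (permutation p = 0.005). The 2508 strongest IDR peaks included 8 of the 15. The top peaks of replicates 1 and 2 alone numbered 14 and 15 there, counted without matching them to the IDR peaks. The IDR peaks ranked 3146 and 3379 had no match in replicate 1. Those ranked 2703, 4467 and 4267 fell below its top peaks, at 5417, 9137 and 24618. In replicate 2 those ranked 3305 and 4705 did, at 8904 and 7170. Some intervals overlap, such as 13004565 to 13004914 and 13004765 to 13005114, so separate regions are fewer than the 15 peaks. The strongest, from 13008882 to 13009265, had a signal of 714.4 (342.7 and 365.7 in replicates 1 and 2) and its summit in an intron 622 bp downstream of the annotated 5′ end. A second intronic summit lay 1361 bp downstream (466.7), and another summit 157 bp upstream (463.5), within the annotated non-coding genes F11C1.12 and F11C1.13. Upstream peaks reached to 8723 bp from the 5′ end, and none of the 15 had the half-site element at its summit. Within 20 kb of unc-119 (III, 10902641 to 10908935) no IDR peak was found, against a mean of 2.63 in random windows. The median over protein-coding genes was 2, so a count of 0 is not far from that of a usual gene. The pooled list held 12 regions around unc-119 (random mean 14.7) and 27 around nhr-25 (random mean 13.9). The labels do not give the segment or the copy number of the tagged nhr-25 insertion, so how many of the reads at this locus come from it is unknown.

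**Figure D4:**
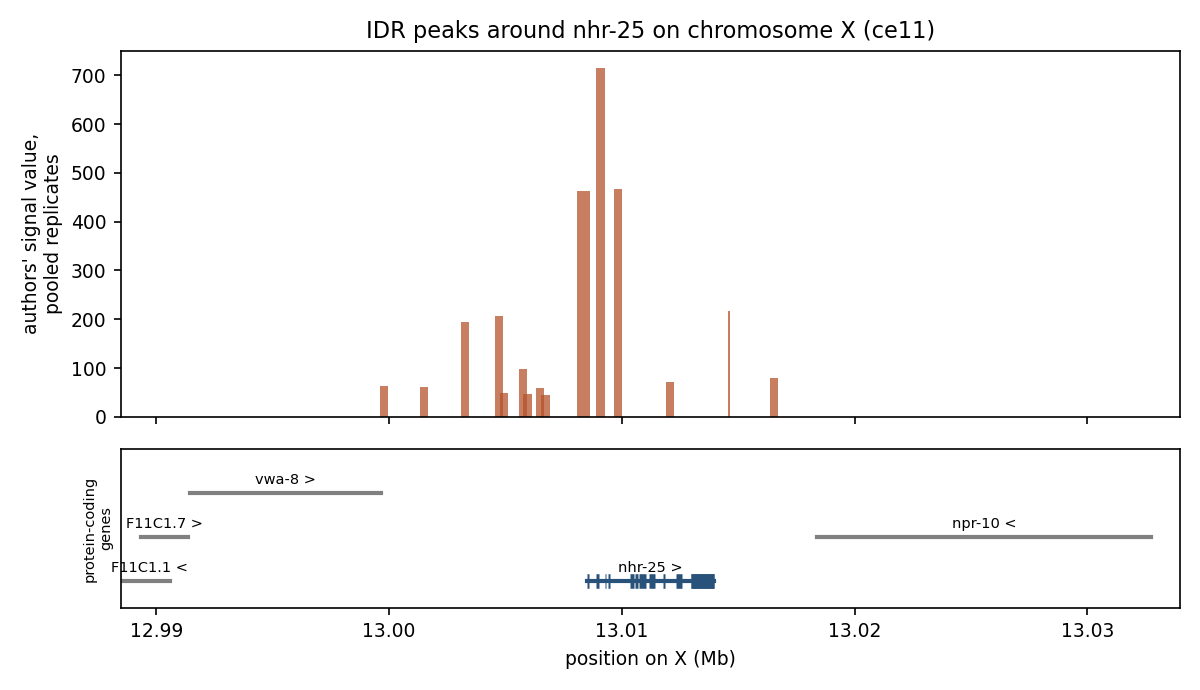
IDR peaks within 20 kb of nhr-25 on chromosome X of ce11. Upper panel: each bar spans a peak (x axis, Mb) and its height is the authors' pooled signal (y axis); overlapping peaks are drawn over one another. Lower panel: protein-coding genes with their strand, and the exons of nhr-25 as thick boxes. The 3 highest bars, 714.4, 466.7 and 463.5, lie at and within the 5′ part of nhr-25.

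tRNA genes lay near a small part of the summits, but well above chance. Summits within 200 bp of a tRNA gene numbered 140 (2.79%, exact 95% interval 2.35 to 3.29), against 0.296% of random positions on average and 0.558% at most (1000 placements, permutation p = 0.001, the smallest they can give). They marked 163 of 612 tRNA genes (26.6%). The replicates differed here, at 2.21% for replicate 1 and 3.39% for replicate 2 (2.80% ± 0.83, SD, n = 2). Among the 2508 strongest IDR peaks the share was lower, at 1.75%. tRNA genes are repeated sequences, so placement of reads among copies is uncertain.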

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

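Direction and side of the threshold were kept under all alternatives run for replicate overlap (56.2% to 76.2%), promoter share (36.97% to 59.97%), X density and the half-site share (2.27% to 6.80%). The same held for peaks around nhr-25 (8 to 15) and summits near tRNA genes (1.75% to 3.39%). Around unc-119 the count stayed 0, which was fixed in advance where a setting used a part of the same peaks or window. Replacing the IDR list by the strongest pooled regions moved nothing, because these are the same peaks. The Spearman correlation between replicate signals was 0.680 with summits within 50 bp, 0.606 within 200 bp and 0.766 over all matched regions, where peaks were not selected on pooled height. The number of lists with more promoter peaks was 8 in the main setting, 4 in the 2508 strongest IDR peaks, 4 and 3 with windows of 1000 and 500 bp upstream, 4 against matched random lists, and 7 or 6 without replicate 1 or 2. Fewer peaks enter in the 2508 strongest and in the shorter windows, but the cause was tested for none of these settings. Odds ratios moved both ways in the 2508 strongest peaks. For junction genes it fell from 4.45 to 1.05, and for heterochronic genes it rose from 5.002 to 7.51. Of the higher lists only ribosomal protein genes passed the threshold in all 8 alternative settings. The single lower list, chemoreceptors, passed in all as well. Of 77 named genes with a promoter peak, 66 had one among the 2508 strongest, 56 and 43 in the shorter windows and 57 with nearest-end assignment, while 75 and 76 had one without replicate 1 or 2. Most of these genes were named for a strong promoter peak, which favours the count of 66. The counts therefore do not stand for genes that were not named. Depth is unknown, so absence of a peak does not show absence of binding.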

Other observations

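Tests described here on gene families, sequence words, the joined word, element position, ribosomal against other ubiquitous genes, upstream length around nhr-25, and the upper limit for the half-site in ribosomal promoter peaks were chosen after results had been seen, and the list of other ubiquitous genes was chosen after the strongest peaks had been seen but before its own share was.

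Beyond the fixed lists, families of genes that share a name were compared in the same way (117 families of at least 15 members; Fisher's exact test with Benjamini-Hochberg adjustment). Promoter peaks were more frequent in 23 families and less frequent in 33. Among the 23, besides the ribosomal rpl and rps genes, the smallest p belonged to the lin genes, named after cell lineage defects (25 of 47, exact adjusted p = 1.38e-06), and the dpy genes, named after a short body, also passed (13 of 25, 1.07e-03); both names span unrelated proteins and overlap the fixed lists. Others were vacuolar ATPase subunits (vha, 13 of 20, exact adjusted p = 6.67e-05), nucleoporins (npp, 14 of 26, 4.59e-04), sec genes of the secretory pathway (10 of 19, 3.71e-03), TFIID subunits (taf, 8 of 17, 1.85e-02) and Mediator subunits (mdt, 9 of 20, 1.73e-02). None of 31 major sperm protein genes (msp) and none of 31 FMRFamide-like peptide genes (flp) had one, which allows up to 11.2% each (exact adjusted p = 1.32e-02), and C-type lectin genes had one in 5 of 240 cases (exact adjusted p = 9.35e-14).

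Ranked by p, the leading words at summits were not those of the half-site. Of 2080 words of 6 bases, counted with their reverse complements within 50 bp of the summits, 791 were more frequent there than in the left flank and 565 less (exact sign tests, adjusted p under 0.05). Among the words more frequent at summits GAGAGA led by p, at 24.9% of summits against 6.64% and 7.39% of flanks. Ranks by p given here leave out the words that were rarer at summits. CGTCTC, CTGCGT, TGCGTC and GCGTCT, which overlap to spell CTGCGTCTC, were among the 7 highest of the more frequent words. That joined word lay at 7.59% of summits against 0.598% and 0.558% of flanks, and at 10.3% of the 1004 strongest peaks against 6.48% of the 1003 weakest. AAGGTC from the half-site ranked 39 by p among the more frequent words (7.46% against 2.17% and 2.35%). A rank by p favours common words. By ratio to the flanks AAGGTC, at 3.275, was near GAGAGA (3.547) and below CGTCTC (4.933). Which proteins bind the leading words was not tested.

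Peaks with the half-site element lay in promoter windows less often than the rest: 82 of 173 (47.4%) against 2788 of 4844 (57.6%; Fisher's exact p = 9.69e-03, two-sided). The strongest of them lay 2421 bp upstream of din-1, which encodes a cofactor of the receptor DAF-12 (II, 11635847 to 11636191, signal 335.5), and 3026 bp upstream of sptf-3 (I, 13369824 to 13370006, 328.9). Another lay in an intron of lin-29, the heterochronic regulator without a promoter peak (II, 11928912 to 11929078, 176.3). In the hbl-1 promoter an element-bearing peak had its summit 1142 bp upstream (X, 5820825 to 5821174, 115.5). These peaks were picked after their values were seen.

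Ribosomal protein genes carried promoter peaks in 90.8% of cases, and 3 explanations were weighed. If accessible promoters of ubiquitously expressed genes were marked in general, other such genes should be marked too: 58.7% of 92 proteasome, Sm protein, vacuolar ATPase, translation factor and chaperonin genes had a promoter peak (odds ratio 6.39, Fisher's exact p = 8.33e-18), which is consistent with that explanation, though their share was below that of the ribosomal genes (Fisher's exact p = 1.76e-06). That contrast used the 2000 bp window, in which a summit can count for several genes. Nearest-end assignment is given for the ribosomal genes only, so the part of the window in the contrast was not tested. Peaks of neighbouring genes counted through the wide window are argued against as the whole cause, since the odds ratio was 7.14 with each summit given to its nearest 5′ end (Fisher's exact p = 1.05e-15). The half-site as the bound sequence in most of these peaks was not decided by the search. The core was present in 2 of the 67 ribosomal promoter peaks (2.99%, exact 95% upper limit 10.4%) and the full element in 0. Most of these peaks thus lacked an exact copy of the core near the summit. Most other promoter peaks lacked one too, and looser matches were not searched, so this does not set ribosomal promoters apart. Whether the core was rarer there than in other promoter peaks (6.17%, 173 peaks) stays open (Fisher's exact p = 0.435), and no control list, expression or accessibility data were used here.

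The run of 15 peaks around nhr-25 was weighed against its long upstream sequence and against the transgene. Long upstream sequence alone is argued against, since 99.5% of 2916 genes with an upstream intergenic length within 2-fold had fewer peaks within 20 kb (median 2, highest 22). Extra copies of the cloned segment may raise coverage over all of it, coding exons included; 26.5% of the coding bases of nhr-25 lay in regions of the pooled list, more than in 89.4% of genes of like coding length but below the 99th percentile of 57.2%. Neither outcome set for this test was met, so copy number and binding of NHR-25 to its own gene cannot be told apart here. Peaks were absent around unc-119, but a rescue gene from another species would add no reads there, so this excludes nothing.

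The enriched half-site raises the hypothesis that promoters of epidermal, molting and collagen genes carry it most often; the hedgehog-related and patched-related list was counted among the epidermal lists. Of the 112 promoter peaks of these 6 lists 5.36% had the element (6 peaks, exact 95% interval 1.99 to 11.3), against 2.76% of the other 2758 promoter peaks (odds ratio 2.00, Fisher's exact p = 0.135, two-sided). The peaks are too few to decide whether the shares differ. The 6 peaks include those of mlt-11, let-653, col-10, col-42, col-80 and, from the hedgehog-related and patched-related list, ptr-14.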
